A study of Danio rerio with 2 samples.

How the data were processed

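Single-cell CEL-seq2 libraries were made from 2 plates of 384 wells each, per the labels' protocols, with cells sorted from dissected and dissociated caudal hematopoietic tissue of wild-type zebrafish at 5 days post fertilization. The labels and layouts also gave a sort day of 6. Reads were aligned with BWA to the genome build Zv9, per the submitters' processing notes. The BWA version, the counting tool and the filters are not given in the sources used here. The deposited tables held expected counts, 1 value per gene and well, not scaled to depth. Of 1273614 values above 0, 100% matched a whole count of molecular identifiers n, corrected for identifiers drawn more than once as ln(1 − n/4096)/ln(1 − 1/4096), within 0.01, and these values are called transcripts. The authors' plate layouts, per the file headers, gave each well's sort class. The layout of plate 20 numbered wells along rows, and the layout of plate 21 listed wells in the same order without numbers, so that numbering along rows was assumed for it. The list of cell barcodes was not used here.

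Spike-in transcripts, 163600 on plate 20 and 188463 on plate 21, were left out of depths and tests. Of 19955 gene IDs, 15742 (78.9%) were paired with a name, and the named genes held 81.5% of transcripts; other genes are given by ID. Many names are those of human genes, and near-identical copies such as the globin genes can share reads. No coordinates are given, since no genome of the build was used here. The paired IDs of kdrl and runx1 were not among the rows used, and both genes were not analysed here. The 21 undefined wells entered no comparison.

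Wells with at least 500 transcripts were kept as cells. No doublet caller was run, since each well was sorted, and 1 well of 249815 transcripts was kept in the main test and left out in an alternative; whether it held more than 1 cell was not tested. Cells are not replicates, and values were summed per plate and class and rounded to whole numbers, giving 4 sums, 2 plates and 1 residual degree of freedom. The labels do not state that the plates came from separate animals, so p-values of single genes measure the spread between plates, which may be technical. Both classes were sorted into each plate, and the plate was therefore a block in the model. Genes were tested two-sided with edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood F test) in R 4.3.3, with Benjamini-Hochberg adjustment, and the SE of a log2 fold was derived from its F value. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, for lists with at least 3 tested members, adjusted over lists. At the preset correlation camera takes genes as its units, so its p-values do not measure the spread between plates. Per-plate folds were computed on TMM-normalized CPM with 1 added.

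The 22 lists, the tests and the rule for named genes were fixed before the data were examined. Lists were matched to names exactly, ignoring case, a rule set after the names were seen and before any test. Named genes were the 5 identity genes kdrl, cdh5, itga2b, runx1 and myb, the 8 with the smallest p in each direction, since fewer than 5 passed, and up to 4 members of each list with the smallest p; a few other list members are named with the lists and were chosen after their values were seen. Cells were clustered with scanpy 1.11.5 on values scaled to 10000 per cell, with 2000 variable genes, 20 principal components, 15 neighbours and Leiden resolution 0.8, leaving out mitochondrial genes and every gene with an unadjusted p under 0.05. A cluster was named from at least 3 detected markers of a list, at least 1 of them among its 10 leading genes and more there than of any other list, and clusters with over 90% of cells from 1 plate kept a number, a limit set after the clusters were seen.

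The edgeR test was run on simulated data with the 8488 genes, 4 sums and the estimated dispersion of 0.0787. It recovered 6% of genes changed 2-fold and 63% of genes changed 4-fold, with 3 false calls. At a dispersion of 0.0150 it recovered 51% and 97%, with 5 false calls. Every simulated gene was given the same dispersion, while dispersions differ between genes in the data. These shares may therefore overstate what the main test recovers. Alternatives fixed beforehand were DESeq2 size factors, DESeq2 1.42.0 with its Wald test, no plate block, cell minimums of 250 and 1000 transcripts, each cell thinned to 500, no filter on low counts, cells over 5% globin left out, an estimated correlation, fry, Leiden resolutions of 0.5 and 1.2 and each plate left out. Added after seeing the data were whole counts recovered from the deposited values, the largest well left out, 15 wells with over 5% muscle or epidermis transcripts left out, and the plate 21 layout read down columns.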

Results

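Single cells of the zebrafish caudal hematopoietic tissue, the embryonic niche in the tail in which blood stem and progenitor cells settle and expand, were profiled at 5 days post fertilization in wild-type animals. Sorted hematopoietic stem and progenitor cells (HSPCs) were placed in 2 plates of 384 wells, and the 3′ ends of their transcripts were counted with molecular identifiers by CEL-seq2. The plate layouts assigned each well to a double (D), a single (S) or an undefined (X) sort class, without stating for which markers the cells were double or single. Of the 384 wells of a plate, 57.8% were double, 39.8% single and 9 wells undefined on plate 20 (replicate 1), and 62.5% were double, 34.4% single and 12 wells undefined on plate 21 (replicate 2). The title of the series concerns loss of kdrl, an endothelial receptor gene, between embryonic and adult HSPCs, and the comparison of double with single cells addresses how the 2 sort classes differ. The layout of plate 21 gave no well numbers, and its wells were taken to be numbered along rows as on plate 20, so every value of plate 21 by class rests on that reading.

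Cells with at least 500 transcripts were kept, which were 300 cells of both classes on plate 20 and, on plate 21, included 89 single cells. Double wells passed more often on both plates, with 85.1% (95% Clopper-Pearson interval 79.8 to 89.5) against 72.5% (64.8 to 79.4) on plate 20 and 77.5% (71.7 to 82.6) against 67.4% (58.7 to 75.3) on plate 21. The median depth of a passing double cell was 7170 transcripts on plate 20 and 9395 on plate 21, and that of a passing single cell was 8257 and 8634. The log2 ratio of the class medians was −0.20 on plate 20 and 0.12 on plate 21, so depth per cell had no common direction. With 2 plates, a permutation of the classes within plates cannot give a p below 0.5, and no test was made. The summed double cells held 1827452 transcripts on plate 20 and 2100731 on plate 21, and the summed single cells 1009324 and 936741. A count of 3 in such a sum corresponds to between 1.43 and 3.2 CPM, the unit of counts scaled to the total of a sum. One double well of plate 20 held 249815 transcripts, of which 20.1% came from muscle genes.

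**Figure D1:**
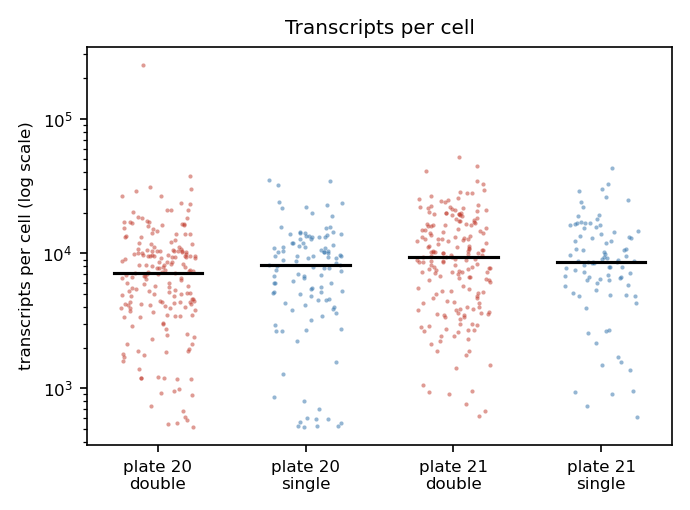
Transcripts per cell on a log axis for the double and single cells of both plates, with 1 point per cell of at least 500 transcripts and a line at each median. The medians lie between 7170 and 9395 transcripts, and 1 double well of plate 20 stands apart at 249815.

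Of the genes chosen to characterise the sort classes, MYB, a transcription factor of blood progenitors, was measured at 326.1 CPM in double and 368.6 CPM in single cells of plate 20 and at 371.8 and 293.6 CPM on plate 21. Its log2 fold, double over single, was 0.06 ± 0.16 (SE, edgeR adjusted p = 0.949), with opposite signs on the 2 plates. The vascular cadherin gene cdh5 had 1 transcript in double and 0 in single cells of plate 20, and 3 and 10 on plate 21. The thrombocyte and HSPC integrin gene itga2b had 1 transcript in all 4 sums together, in single cells of plate 20. Both genes were removed by the filter on low counts and were not tested in the main fit. With no filter, edgeR gave an adjusted p of 0.962 for cdh5 and 0.987 for itga2b. Values for kdrl and runx1 were not analysed here.

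The 8 genes with the smallest p-values in each direction are given here, and none of them passed the test over all genes. The actin-binding genes tmsb4x (ENSDARG00000077777), LCP1 (ENSDARG00000023188) and CORO1A (ENSDARG00000054610) had log2 folds of 1.04 ± 0.09, 1.70 ± 0.16 and 1.65 ± 0.17 (SE, n = 2 plates), and the chemokine receptor gene CCR9 (ENSDARG00000055186) one of 2.23 ± 0.22. Each was higher in double cells on both plates, with tmsb4x at 2684 against 1293 TMM-normalized CPM on plate 20 and at 2404 against 1186 on plate 21. The gene models si:dkey-238c7.12 and ENSDARG00000044129 had folds of 0.73 ± 0.08 and 1.97 ± 0.23, and a gene with no paired name, ENSDARG00000091078, had 2.07 ± 0.22. Lower in double cells were the embryonic alpha-globin gene hbae3 at −0.86 ± 0.11, the globin gene annotated HBE1 (ENSDARG00000045143) at −0.71 ± 0.10, the ammonium transporter gene RHBG at −2.32 ± 0.29 and the keratin gene krt18a.1 at −2.88 ± 0.37. The gene icn2 had 3 and 0 transcripts in double cells and 65 and 11 in single cells of plates 20 and 21, and the ion pump subunit gene ATP1B1 (ENSDARG00000076833) had 0 and 3 against 16 and 27. Of the unnamed genes, ENSDARG00000061219 had a fold of −1.81 ± 0.21, and ENSDARG00000092899 had 3 and 5 transcripts in double against 16 and 75 in single cells. The myosin gene myhz2 had 1434 transcripts in double and 24 in single cells of plate 20 and 0 in both classes of plate 21. Its log2 fold was −0.62 without the well of 249815 transcripts.

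No single gene passed the main test. Of 8488 genes, edgeR's quasi-likelihood test called 0 at an adjusted p under 0.05, with a smallest adjusted p of 0.234. In the same test 724 had an unadjusted p under 0.05 and DESeq2's Wald test called 28, 14 in each direction. The call of 0 did not hold without 15 wells that had over 5% of their transcripts from muscle or epidermis genes, an exclusion chosen after seeing the data. Without them 58 genes were higher and 28 lower in double cells. Leaving out the 249815-transcript well alone gave 0, with a smallest edgeR adjusted p of 0.069.

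Tested as groups, the myeloid progenitor, neutrophil and macrophage lists rose in double cells with the preset correlation. Each had an adjusted p = 0.533 with an estimated correlation in camera. That form rests here on 1 residual degree of freedom and could hardly call any list. The preset form compares genes inside a list with the other genes, and its p-values do not measure the spread between plates. All 8 tested genes of the myeloid progenitor list were higher, with a median log2 fold of 1.505 and an adjusted p of 4.66e-12 in limma's camera test. They included the granulocyte and macrophage transcription factor genes CEBPA at 2.76 ± 0.34, spi1a at 1.51 ± 0.25 and CEBPB at 1.496 ± 0.29. None passed over all genes tested, and 7 passed when adjusted over the list alone. In the neutrophil list 10 of 11 tested genes were higher (median 1.29, camera adjusted p = 3.15e-09), among them the protease genes npsn at 1.28 ± 0.22, MMP9 at 1.29 ± 0.24 and mmp13a at 0.96 ± 0.20, and 10 passed when adjusted over the list alone. Of 23 macrophage genes matched by name, 10 were tested and all 10 were higher (median 1.04, camera adjusted p = 6.09e-07), including the cathepsin genes ctss2.1 at 1.25 ± 0.21 and ctss2.2 at 2.15 ± 0.40 and the lysozyme gene lygl1 at 1.999 ± 0.35, and 5 passed when adjusted over the list alone. Only 7 of the 10 had the same sign on both plates, and the copies of MFAP4 were at 3.60 and 2.72 on plate 20 and at −1.30 and −3.32 on plate 21. The macrophage gene MPEG1 (ENSDARG00000055290) was at 0.05 ± 0.48, with 0.13 on plate 20 and −0.18 on plate 21. The medians were positive on each plate for all 3 lists, at 1.07 and 1.47 for myeloid progenitor, 0.89 and 1.59 for neutrophil and 1.53 and 0.81 for macrophage genes on plates 20 and 21. Some lists share members, such as srgn in the neutrophil and the myeloid progenitor list.

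Inflammatory signalling genes rose as a list, with 10 of 12 tested genes higher (median 0.46, camera adjusted p = 0.0013), and 3 passed when adjusted over the list alone. The plate medians were 0.60 on plate 20 and 0.20 on plate 21, and the list had a camera adjusted p = 0.586 with an estimated correlation. These 3 were the NF-kB subunit gene REL at 1.205 ± 0.22 and the NF-kB inhibitor genes TNFAIP3 at 0.92 ± 0.18 and nfkbiaa at 0.84 ± 0.19. All 5 tested lymphoid genes were higher (median 0.96, with 0.35 on plate 20 and 0.72 on plate 21, camera adjusted p = 0.0104), including the interleukin receptor genes il2rga at 1.11 ± 0.40 and il2rb at 1.36 ± 0.51, and 0 passed when adjusted over the list alone. With an estimated correlation the lymphoid list, like the next one, had an adjusted p = 0.533. The list of HSPC transcription factors and surface genes was called higher (camera adjusted p = 0.0135) with a median of only 0.08 and a mean of 0.51. Its 3 genes that passed when adjusted over the list alone were the pan-leukocyte gene ptprc at 1.65 ± 0.23, the myeloid factor gene SPI1 at 1.13 ± 0.23 and cd34 at 1.47 ± 0.37, while the stem cell factor genes TAL1 at −0.14 ± 0.13 and LMO2 at −0.05 ± 0.15 were not called. With each cell thinned to 500 transcripts the HSPC list was not called (adjusted p = 0.728).

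Erythroid genes fell in double cells as a list, with 22 of 23 tested genes lower (median −0.48, camera adjusted p = 0.000108) and a median of −0.32 on plate 20 and −0.60 on plate 21. The camera result was an adjusted p = 0.533 with an estimated correlation. The heme synthesis gene alas2 was at −0.84 ± 0.13, the red cell carbonic anhydrase gene cahz at −0.72 ± 0.11 and hbae1.3 at −0.77 ± 0.12, and 14 genes passed when adjusted over the list alone. Cells with over 5% of their transcripts from globin genes made up 21.7% (95% Clopper-Pearson interval 16.04 to 28.3) of double and 36.04% (27.1 to 45.7) of single cells on plate 20 and 19.4% (13.9 to 25.8) and 46.1% (35.4 to 56.96) on plate 21. With these cells left out the list was not called (median −0.18, adjusted p = 0.299). Globin genes such as hbae3 are members of the list, so this exclusion selects on the values tested, and a smaller fold was built in.

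Markers of epidermis and stroma fell in double cells with the preset correlation. Both lists had an adjusted p = 0.533 with an estimated correlation in camera. All 10 tested epidermis genes were lower in double cells (median −1.48, camera adjusted p = 3.15e-09), with krt4 at −1.73 ± 0.40 and krt8 at −0.96 ± 0.17, and 7 passed when adjusted over the list alone. The epidermis median was −2.45 on plate 20 and −0.61 on plate 21, and −0.45 without the 15 wells, where krt4 was at −0.50 and the epidermis gene cfl1l at 0.65 instead of −0.89. Those wells were chosen by their share of muscle or epidermis genes, so leaving them out selects on the values of both lists. All 6 tested stromal genes, of 15 matched by name, were lower (median −1.61, camera adjusted p = 1.41e-07; −0.659 over the list with no filter on low counts), with the matrix genes SPARC at −1.55 ± 0.24 and COL1A2 at −1.67 ± 0.26, and 4 passed when adjusted over the list alone. The stromal median was −2.03 on plate 20 and −1.10 on plate 21. Muscle genes had a median of 3.28 on plate 20 and −3.97 on plate 21 and were not called (adjusted p = 0.823). They were called lower without the well of 249815 transcripts (median −2.055, camera adjusted p = 1.98e-06) and with each cell thinned (0.00678). Leaving out only that double well kept 1 single well of plate 21 with 42698 transcripts, of which 29.98% came from muscle genes. How far the call rests on this single well was not tested. Without the 15 wells, with the limit above, the adjusted p was 0.000743.

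**Figure D2:**
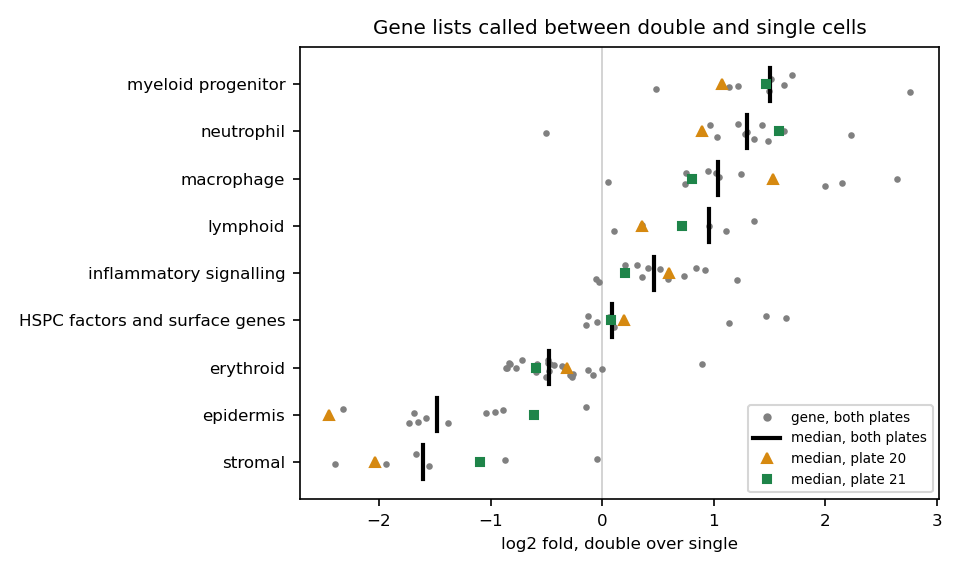
Log2 folds, double over single, of the tested members of the 9 called gene lists, with 1 grey point per gene, a bar at the median of both plates, and a triangle and a square at the medians of plate 20 and plate 21. Each list's plate medians lie on the same side of 0, and the medians of both plates run from −1.61 for the stromal to 1.505 for the myeloid progenitor list.

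Of the 18 lists that could be tested, 6 rose and 3 fell. None of these 9 calls held with an estimated correlation, where the adjusted p was 0.586 for inflammatory signalling and 0.533 for each of the other lists. The fry test, which tests a set against no change, called none. Camera with an estimated correlation, like fry, rests on the 1 residual degree of freedom, so hardly any list could pass in either. Myeloid progenitor (−0.071), lymphoid (−0.2) and HSPC genes (−0.143) had an estimated correlation below the preset 0.01, and still an adjusted p of 0.533 in camera. The other called lists lay above it. They were at 0.6 for epidermis, 0.394 for inflammatory signalling, 0.333 for stromal, 0.289 for macrophage, 0.194 for erythroid and 0.127 for neutrophil genes. For these the preset assumed less correlation than was estimated, and the estimates rest on 1 residual degree of freedom too. The estimated correlation and fry therefore do not decide whether the calls hold. Read down columns instead of along rows, the plate 21 layout kept 5 calls, and neutrophil (adjusted p = 0.0953), lymphoid (0.0549), stromal (0.193) and HSPC genes (0.193) were not called. Lists not called in camera were HSC maintenance (adjusted p = 0.485), thrombocyte (0.936), cell cycle (0.357), cytosolic ribosomal protein (0.322), nuclear-encoded oxidative phosphorylation (0.782), glycolysis (0.617), immediate-early and heat shock (0.0705) and embryonic and fetal programme genes (0.0626). Immediate-early and heat shock genes, a list of dissociation stress, had a median of −0.15 and were called lower in double cells without the well of 249815 transcripts (median −0.72, adjusted p = 0.0014), without the 15 wells (0.00629) and without globin-rich cells (0.019). Over all alternatives with the preset correlation their adjusted p ran from 0.0014 to 0.857. Without the 15 wells, cell cycle (median −0.14, adjusted p = 0.0143) and ribosomal protein genes (−0.06, 0.028) were called lower and glycolysis genes (0.41, 0.0087) higher. Embryonic and fetal programme genes were called lower with no filter on low counts (0.0184) and without globin-rich cells (0.0305). They were not called without the 15 wells (median −0.02, adjusted p = 0.98) or with the plate 21 layout read down columns (median 0.149, adjusted p = 0.895). After the filter on low counts, 2 of 18 endothelial, 2 of 12 Notch, 1 of 8 neural and 1 of 7 pigment members were left, too few for the test. With no filter on low counts the endothelial list was tested and called lower in double cells (median −1.69, camera adjusted p = 5.21e-07). Its transcripts were at 47.1 CPM in double and 46.6 CPM in single cells of plate 20, and at 54.3 and 237.2 CPM on plate 21, where 1 well held 46.4% of those in single cells. In that setting Notch (0.46), neural (0.221) and pigment genes (0.2) were not called. In the main test the log2 folds of these members were −2.49 for SOX7, −0.05 for DAB2, 1.39 for GPR183, 0.44 for notch2, −0.29 for rtn1b and 2.35 for pmela. The plates had opposite signs for pmela (2.74 on plate 20 and −0.75 on plate 21), rtn1b (1.34 and −1.69), notch2 (−0.08 and 1.06) and DAB2 (0.15 and −0.25).

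Clustering the cells without the genes that differed between classes at an unadjusted p under 0.05 gave 7 clusters. A neutrophil-like cluster of 57 cells had npsn, si:dkey-21e2.16, lyz and mmp13a among its 10 leading genes. It held 12.7% (95% Clopper-Pearson interval 8.31 to 18.3) of double and 5.41% (2.01 to 11.4) of single cells on plate 20. On plate 21 it held 10.8% (6.69 to 16.1) and 7.87% (3.22 to 15.5). At Leiden resolution 0.5 the difference, double minus single, was 2.588 points on plate 20 and −0.193 on plate 21. With the genes left out above also used, the neutrophil-like cluster had 49 cells. There si:dkey-21e2.16 led a separate unnamed cluster of 62 cells, at 0.273 times the neutrophil transcripts of the other cells. The 57 cells may therefore include another cell type. An epidermis-like cluster of 14 cells, led by krt5 and with the stromal gene COL1A2 also among its 10 leading genes, held 1.06% (0.128 to 3.77) of double and 4.50% (1.48 to 10.2) of single cells on plate 20 and 2.15% (0.589 to 5.41) and 3.37% (0.701 to 9.54) on plate 21. Cluster 0, of 80 cells led by NAB1 (ENSDARG00000042940) and rgs18 and left unnamed, held 16.4% (11.4 to 22.5) of double and 7.21% (3.16 to 13.7) of single cells on plate 20 and 18.8% (13.5 to 25.2) and 6.74% (2.51 to 14.1) on plate 21. Cluster 3, of 20 cells with a median of 1210 transcripts, was led by genes that include aox5 and PTS and held 1.06% (0.128 to 3.77) of double and 9.91% (5.05 to 17.04) of single cells on plate 20 and 1.61% (0.334 to 4.64) and 4.49% (1.24 to 11.1) on plate 21. Relative to the other cells, its highest list was pigment cell genes, above neural (70.5 times) and stromal genes (26.5 times). It met the naming rule for no list and stayed unnamed. The pigment list held 230 transcripts in all, and how many wells carry its ratio was not tested. Its 1 gene in the main test, pmela, was higher in double cells, with opposite signs on the plates. Clusters 1 and 4 split by plate, with 95.9% and 95.8% of their cells from 1 plate. Erythroid genes made up a median of 3.91% of transcripts in cluster 1 and 3.295% in cluster 4. Muscle genes such as pvalb1 led cluster 1, at a median of 0.367%, close to the 0.379% of all passing cells of plate 20. The pair together held 61.9% (54.6 to 68.9) of double and 72.1% (62.8 to 80.2) of single cells on plate 20 and 66.7% (59.4 to 73.4) and 76.4% (66.2 to 84.8) on plate 21. A cluster of 15 cells, 93.3% from plate 20, was led by MFAP4 (ENSDARG00000088745) and had 3 macrophage genes among its 10 leading genes. It was kept by number, under a limit of 90% from 1 plate that was set after the clusters were seen, and held 6.88% (3.71 to 11.5) of double and 0.901% (0.023 to 4.92) of single cells on plate 20 and 0% and 1.12% (0.028 to 6.10) on plate 21. In this clustering the count of 0 double cells on plate 21 allows a share of up to 1.96% at the upper bound of the exact interval. With at least 1000 transcripts per cell, a macrophage-like cluster of 41 cells held 10.7% (6.55 to 16.2) of double and 3.03% (0.629 to 8.60) of single cells on plate 20. On plate 21 that cluster held 8.33% (4.74 to 13.4) and 4.76% (1.31 to 11.7). At Leiden resolutions 0.5 and 1.2 macrophage-like clusters differed, double minus single, by 5.977 points on plate 20 and −0.634 on plate 21. Intervals cover counting error only, the sort itself can set these shares, and no test across 2 plates was made.

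**Figure D3:**
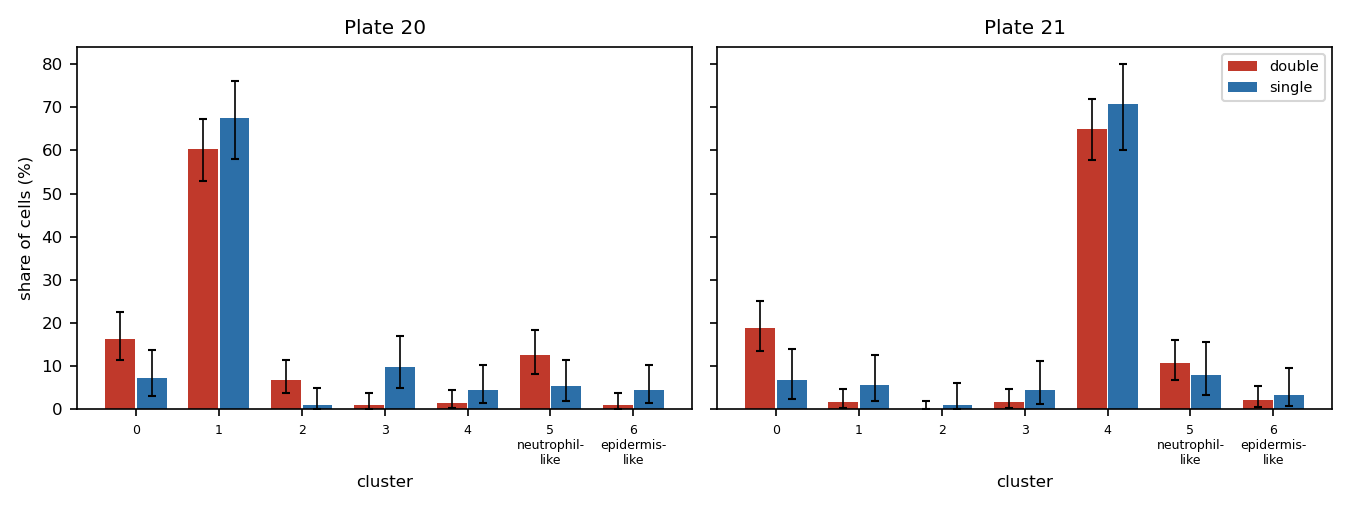
Share of the double and single cells of each plate in each of 7 clusters, in percent, with exact 95% binomial intervals as error bars. The neutrophil-like cluster holds 12.7% of double and 5.41% of single cells on plate 20, and 10.8% and 7.87% on plate 21.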

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

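Wells that the layouts marked as undefined entered no comparison, yet 7 of 9 on plate 20 and 9 of 12 on plate 21 held at least 500 transcripts, as many as the cells compared were required to hold. Erythroid genes made up a median of 0.705% of their transcripts on plate 20 and 0.754% on plate 21, with a highest share of 19.8% in a well of plate 21. Neutrophil genes made up a median of 0.150% and 0.079%. No biological explanation was tested, since the layouts give no class for these wells.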

How the results depend on the processing

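The alternatives that used recovered whole counts, left out the largest well or 15 wells, or read the plate 21 layout down columns were chosen after seeing the data. For single genes, the count of 0 in edgeR was also 0 with DESeq2 size factors, no replicate block, at least 250 or 1000 transcripts per cell, cells over 5% globin left out, recovered whole counts and without the largest well. It was 31 (3.555% of 872 genes tested) with each cell thinned to 500 transcripts and 1.88% of 19707 genes with no filter on low counts. It was 28 (0.33%) with DESeq2's Wald test, where 2469 adjusted p-values were not given. It was 86 (1.07%) without the 15 wells and 3 (0.03565%) with the plate 21 layout read down columns. The cause was not tested except for the 86, where the test did not settle it. For gene lists, the count of 9 was 14 without the 15 wells, which added cell cycle, ribosomal protein, glycolysis, heat shock and muscle genes; those wells were selected on muscle and epidermis genes, so these 2 lists are not tested independently there. An estimated correlation and fry gave 0 each, and both rest on 1 residual degree of freedom, where hardly any list could pass. The count was 5 with the layout of plate 21 read down columns, and the cause was not tested. It was 11 with no filter on low counts, adding endothelial and embryonic genes, 11 without the largest well, adding heat shock and muscle genes, 10 without globin-rich cells and 7 with each cell thinned, where 13 lists were tested. Over the remaining settings, 77 of 79 combinations of a called list and a setting kept call and direction. The exceptions were HSPC genes with each cell thinned and erythroid genes without globin-rich cells, which selects on members of that list. With the layout read down columns and without the 15 wells included, it was 91 of 97, and none changed direction. The replicate block changed no call of a gene, and with no replicate block the 9 called lists kept their calls. With 1 plate left out there is no test, and the 9 called lists kept their sign on each plate. The log2 ratio of transcripts per cell was −0.041, and ranged from −0.204 to 0.122 with a plate left out. The double minus single share of the neutrophil-like cluster, 5.09 points, was 1.2 at Leiden resolution 0.5, with opposite signs on the plates (2.588 on plate 20 and −0.193 on plate 21) and the cause not tested, and 2.60 with at least 1000 transcripts per cell. With that minimum a further cluster of 77 cells was larger in double cells by 9.29 points. It met the naming rule for stromal cells by 1 gene, col1a1a, beside the leading genes NAB1 (ENSDARG00000042940) and CCR9, and is therefore read neither as stromal nor against the lower stromal list. Macrophage-like clusters differed by 2.67 points at both Leiden resolutions 0.5 and 1.2, which is 5.98 on plate 20 and −0.63 on plate 21, and by 5.61 with at least 1000 transcripts, and an erythroid-like cluster at resolution 1.2 by −4.38. With a plate left out the neutrophil-like difference ranged from 2.89 to 7.29 points, and that of the epidermis-like cluster, −2.33 points, from −3.45 to −1.22. No alternative gave a value for kdrl. With the same 4 sums and 1 dispersion for all genes, the simulation recovered 6% of genes changed 2-fold at 0.0787 and 51% at 0.0150. The spread between plates therefore limits what can be detected, and these shares may be too high for the data.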

Other observations

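The tests of spill from the largest well, of depth, and every layout check except the first were chosen only after results were seen. Among genes not described above, the 86 called without the 15 wells, an exclusion chosen after seeing the data, included the chemokine receptor gene CXCR4 (ENSDARG00000041959) at a log2 fold of 1.18, the actin regulator genes ARPC1B at 1.301 and COTL1 at 1.16, the immune kinase gene SYK at 1.996 and the GTPase gene rac2 at 1.37, all higher in double cells. Lower were the band 3 anion exchanger gene SLC4A1 (ENSDARG00000012881) at −0.56, the ferritin gene fth1a at −0.40 and the heat shock gene hsp70l at −1.46. These genes were picked from that list after their values were seen.

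The step from 0 to 86 called genes may come from a few wells of other cell types that widened the spread between plates. The 15 wells held 14.3% of the transcripts of double cells on plate 20 and 4.90%, 1.81% and 6.96% of the other sums, and the dispersion was 0.0787 with them and 0.0150 without them. In 20 random removals of as many wells per plate and class, 0 gave as many calls. Of these removals, 19 gave 0 calls and 1 gave 2. All were drawn from the other wells, so each kept the 15 wells, and the dispersion stayed between 0.0773 and 0.0842. They matched the number of wells and not the transcripts. The removals therefore cannot tell wells of other cell types from a few deep wells. The 5% limit was set on the same data. Leaving out the largest well alone gave 0 calls, but the dispersion fell to 0.0313 and the smallest edgeR adjusted p to 0.069.

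Leukocyte lists were called higher and the erythroid list lower in double cells only with the preset correlation, neutrophil and lymphoid genes only along rows. With an estimated correlation the camera adjusted p was 0.533 to 0.586, on 1 residual degree of freedom that could hardly give a call. For these calls, 3 explanations were weighed. The tables argue against depth per cell, since at the preset correlation all 4 of the called leukocyte and erythroid lists that could still be tested kept call and direction with each cell thinned to 500 transcripts; macrophage and lymphoid genes could not be tested there, and over all 7 testable lists 6 kept their call. A different mix of clusters may account for the leukocyte part, and it cannot be told apart from a change within clusters. Weighting the classes to the same mix left 4.1% of the leukocyte median on plate 20 (1.18 to 0.048). On plate 21 it left 85.5% (0.785 to 0.671). The weighting used 6 clusters on plate 20 and 5 on plate 21, so these shares cannot be compared between plates. The cluster led by MFAP4 held 13 double cells and 1 single cell on plate 20, and 0 double cells on plate 21. What was left on plate 20 may therefore rest on very few cells. The erythroid median went from −0.45 to −0.27 on plate 20 and from −0.70 to −0.57 on plate 21. Clusters 1 and 4 were weighted as 1 cluster, so a different erythroid mix within that pair was not adjusted for. What was left therefore does not decide between mix and change within clusters. No spread was computed for any of these medians. That the sort classes themselves differ in lineage stays open, and the markers behind them are not given in the labels.

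Numbering of plate 21 down columns also stays open, and the check was run in several forms. The form written beforehand compared fold changes of both plates across 3130 genes, which are not independent replicates, with all wells and 20 random assignments of the layout, and it did not decide: the correlation was −0.330 along rows and −0.471 down columns, a difference of 0.141, but 15 of 20 random assignments were as high as the rows and the highest was 0.703. Chosen after that result, the same correlation without the 15 wells was 0.401 along rows and 0.245 down columns, against a highest of 0.376 in 20 and 0.400 in 100 random assignments. A further measure, also chosen after the first result, was the leukocyte minus erythroid median log2 fold on plate 21, at 1.46 along rows and 0.252 down columns with all wells (highest of 100 random assignments 0.828) and at 1.52 and 0.274 without the 15 wells (highest 0.897). Its lists had been called partly from plate 21 read along rows, so it is not independent evidence for that reading.

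Muscle genes made up a median of 0.379% of transcripts in passing wells of plate 20 and 0.095% on plate 21. Free or exchanged muscle RNA that does not scale with a well's own transcripts may be their source. Wells of plate 20 with over 5% muscle transcripts or with no transcripts were left out here, and undefined wells were included. The 5% limit selects on the value compared. The median muscle share was 1.90% in 74 wells under 500 transcripts and 0.378% in wells at or above it. The ratio was 5.03 (95% bootstrap interval 3.87 to 6.09). Spill from the largest well of that plate cannot be told apart from another source: the muscle profile of the other wells lay closer to that well than to the muscle-rich well of plate 21 by a distance of 0.025 (0.024 to 0.026), but the other wells of plate 21 leaned the same way by 0.018. No biological explanation was tested.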
